A study of Micractinium conductrix and Chlorella sorokiniana with 12 samples.

How the data were processed

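The series measured polyadenylated RNA from whole-cell lysates of the green algae Micractinium conductrix and Chlorella sorokiniana, each grown at pH 5.7 and at pH 7.6. Each species was a single strain, from the SAG collection for M. conductrix and the UTEX collection for C. sorokiniana. The labels name a modified freshwater SAG medium for M. conductrix and a modified freshwater medium for C. sorokiniana. Per the labels' protocols, cells were pelleted and frozen, RNA was extracted with Trizol, treated with DNase, selected on oligo(dT) beads, fragmented, primed with random primers and sequenced on an Illumina HiSeq instrument. Each of the 4 groups held 3 libraries, 12 in all. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, Picard and Cuffnorm, with no version, and the genome build, the gene models and whether counting used strand are not given in the sources used here. The deposited values are FPKM, fragment counts scaled to gene length and library size, in 1 table per species, unpooled, with 1 column per library. The libraries of a table had alike medians but unlike sums, and the sources used here do not say how the authors scaled the deposited FPKM values between libraries. FPKM are not counts, so reads shared between paralogs or overlapping genes could not be judged.

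Genes carried only running identifiers (g1, g2 and so on), numbered separately in each species. The files pair them with no gene name, product or position, and no genome or annotation was used here. The planned tests of 26 gene lists chosen by product name, and the comparison of orthologs between the species, therefore could not be run, and up to 2 genes that rose and 2 that fell are named per species.

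The table of M. conductrix held 9349 genes, of which 8500 had a mean of at least 1 FPKM over the 6 libraries and were tested. The table of C. sorokiniana held 9587 genes, of which 9011 were tested. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), pH 5.7 minus pH 7.6, 2-sided, separately in each species, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Permutations and the other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No label says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

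Libraries are called here by the number in their name, which was 2, 4 and 57 at pH 5.7 and 1, 3 and 76 at pH 7.6 in both species. The fit without a block, and the alternatives to it, were fixed before the data were examined. The groups shared no number, but a fit with 1 and 2, 3 and 4, and 57 and 76 as pairs was fixed at the same time. The first 4 are consecutive numbers, and 57 and 76 match the growth pH written without its point. The names were the only source of this pairing. Deviations from the group mean then correlated within every pair, across genes, by 0.60, 0.66 and 0.59 in M. conductrix and by 0.40, 0.58 and 0.48 in C. sorokiniana. Of the 6 ways to match the libraries of both pH groups, this one had the highest mean correlation in each species (0.62 against at most 0.03, and 0.49 against at most 0.13), and every library correlated best with its partner. Deviations cancel out within each pH group, so a high value for 1 matching lowers those of the others, and the gap is partly arithmetic. The libraries were treated as paired because of these correlations, and both fits are given wherever they differed.

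Both fits were tested on simulated log2 values with the genes, means, pair differences and residual spread of each species and 200 changed genes, 50 at each of 4 sizes. In the M. conductrix simulation of 8500 genes, the unpaired fit recovered 32% of genes changed by 1 on the log2 scale and 86% of those changed by 2, and the paired fit 90% and 100%. In the C. sorokiniana simulation of 9011 genes, the unpaired fit recovered 0% at 1, 12% at 2, 60% at 3 and 78% at 4, and the paired fit 8%, 82%, 100% and 100%. The same simulated values before any change was added gave the share of genes whose pH groups did not overlap by chance. This value was added after the data were seen. The simulated pair differences were the fitted ones, which include residual spread, so this share may be too low. False calls were 0 without the pairing, and 16 of 211 and 12 of 157 calls with it, for M. conductrix and C. sorokiniana. The simulated noise was normal, independent between genes, the same for all libraries of a gene, and drawn once. Its spread came from the paired fit with its mean-variance trend. Recovery and false calls therefore hold under the assumptions of that fit and may be worse in the real data.

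The files hold no read totals, so the depth of a library is unknown and no counting interval was computed. Relative depth was estimated from the steps between values under 1 FPKM, where whole reads give whole multiples of 1 unit. Pairs of low values lay at small whole-number ratios, within 0.01 on the log2 scale, in 18.1% of cases in M. conductrix. For shifted units the share was 2.39%. The units were chosen to raise this share and the shifted ones were not refitted, so this does not show how exact the estimates are. Relative to the shallowest library of M. conductrix, library 4, the estimates were 1.49 for library 2, 3.27 for 57, 1.97 for 1, 1.88 for 3 and 4.01 for 76. For C. sorokiniana the estimates lay between 1 and 1.56, but that of library 57 differed by a factor of 2 between ways of resolving the steps, so they are less certain.

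Alternatives were a pseudocount of 0.1 or 5 FPKM, no filter or a mean of at least 5 FPKM, upper-quartile scaling, quantile normalization, scaling to equal totals, no mean-variance trend, sample quality weights, a requirement of at least a doubling or halving, each library left out, the pairs as a block, and the naming style (numbered 1 to 4, or 57 and 76) as a covariate. Added after the data were seen were the same alternatives in the paired fit, each pair left out, and the numbered libraries alone. Named genes had to have an adjusted p under 0.05, groups that did not overlap and at least 5 FPKM in the higher group, and the 2 largest rises and falls were taken. In C. sorokiniana, where the unpaired fit called no gene, the rule was applied to the paired fit, with the same direction in 3 of 3 pairs in place of separate groups, which was chosen after the values were seen.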

Results

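Transcript levels were profiled in a pair of green algae, each grown at an acidic pH of 5.7 and at a near-neutral pH of 7.6. Micractinium conductrix was obtained as an endosymbiont of the ciliate Paramecium bursaria, and Chlorella sorokiniana is a free-living relative. The study addressed the release of the disaccharide maltose by a green alga, a trait known of symbiotic Chlorella-type algae in acidic medium, so the comparison of growth pH within each species asks which genes change with that condition. Each species had 3 libraries per pH. Library medians were alike within a species, at 27.2 to 28.1 FPKM in M. conductrix and 19.7 to 21.4 FPKM in C. sorokiniana. Between 8300 and 8494 genes reached 1 FPKM in each M. conductrix library, and between 8498 and 8942 in each C. sorokiniana library. Absolute depth is unknown, and libraries 57 and 76 of M. conductrix were estimated to be the deepest of that species.

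Libraries grouped by pH and, in both species, by the pairs read from their names (1 and 2, 3 and 4, 57 and 76). In M. conductrix, growth pH accounted for 39.5% of the variance of log2(FPKM + 1), the pairs of libraries for 48.4%, and 12.1% was left. In C. sorokiniana the shares were 26.7%, 54% and 19.3%. The pairs and the remainder each hold more degrees of freedom than pH, and libraries without any structure would also give each part a share. These shares therefore do not rank pH against the pairs. The first principal component of M. conductrix, with 46.1% of the variance, placed each pH 5.7 library above its pH 7.6 partner, while the second, with 26.6%, separated libraries 57 and 76 from the numbered 4. In C. sorokiniana the order was exchanged: the first component (41.1%) separated libraries 57 and 76 from the others, and the second (31.8%) placed each pH 7.6 library above its pH 5.7 partner. The median SD within pH groups was 0.25 on the log2 scale in M. conductrix and 0.53 in C. sorokiniana.

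**Figure D1:**
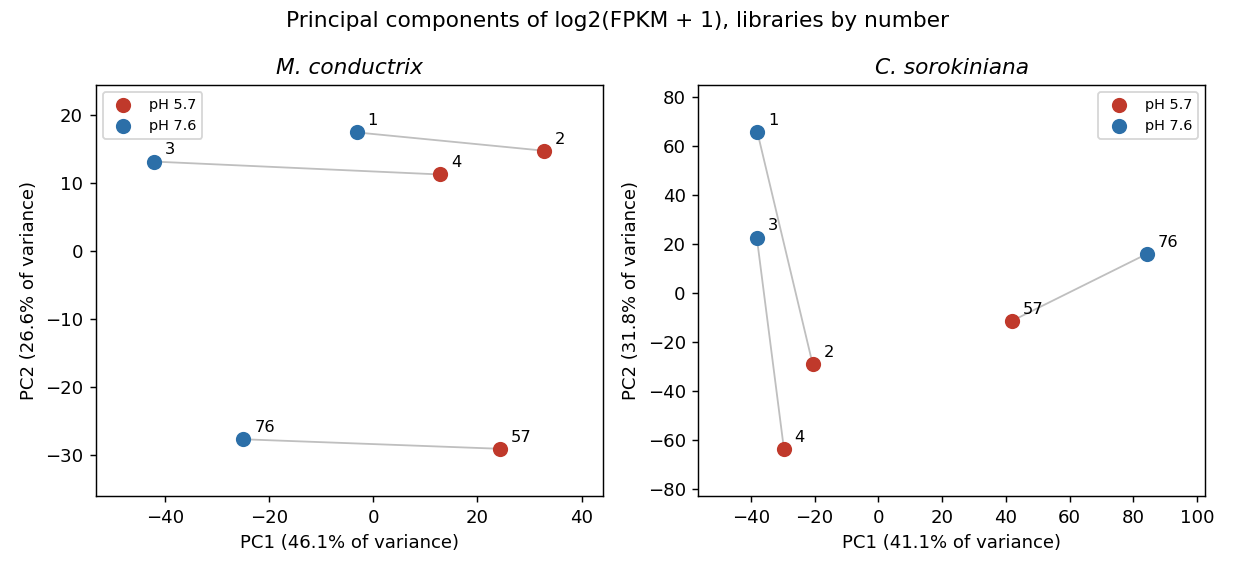
Each point is a library, labelled by its number, on the first 2 principal components of log2(FPKM + 1), with pH in colour and grey lines joining the libraries of a pair. In M. conductrix the lines run along PC1 (46.1% of the variance), and in C. sorokiniana libraries 57 and 76 lie apart from the other 4 on PC1 (41.1%).

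In M. conductrix, 95 of 8500 genes changed with growth pH, 23 of them higher and 72 lower at pH 5.7 (limma, Benjamini-Hochberg adjusted p under 0.05, no pairing). The higher genes had a median log2 fold of 1.56 and the lower genes of -1.82, and 22 of the 23 and 67 of the 72 changed by at least a doubling or halving. Among the lower genes, 9 fell at least 16-fold, from a median of 311 FPKM at pH 7.6 to 2.62 FPKM at pH 5.7. All 9 fell in each of the 3 pairs of libraries, by 2.31 or more on the log2 scale. Only 1 of these higher genes, g1861, rose by as much. Among the genes called within pairs, 2 rose and 11 fell at least 16-fold.

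Of the 4 genes named here, g6354, g7305 and g1861 averaged under 3 FPKM at one pH and over 100 FPKM at the other. Gene g6354 was at 894 ± 501 FPKM (SD, n = 3) at pH 7.6 and at 2.62 ± 4.21 FPKM at pH 5.7, a log2 fold of -8.39 (SE 0.86; limma adjusted p = 0.0102). Its values were 1270, 1080 and 327 FPKM in libraries 1, 3 and 76, against 0.127, 7.47 and 0.25 FPKM in libraries 2, 4 and 57. Gene g7305 was at 416 ± 46.5 FPKM at pH 7.6 and at 1.4 ± 1.9 FPKM at pH 5.7 (log2 fold -7.71, SE 0.48; limma adjusted p = 0.00108). In the opposite direction, g1861 was at 193 ± 41.9 FPKM at pH 5.7 and at 1.33 ± 2.23 FPKM at pH 7.6, a log2 fold of 6.77 (SE 0.59; limma adjusted p = 0.005). Most of its signal at pH 7.6 was in library 1, with 3.91 FPKM, against 0.0512 and 0.0358 FPKM in libraries 3 and 76. Gene g6744 was at 30.8 ± 6.27 FPKM at pH 5.7 and at 3.68 ± 1.23 FPKM at pH 7.6 (log2 fold 2.78, SE 0.27; limma adjusted p = 0.00785). The size of these folds depended on the pseudocount: with 0.1 and with 5 FPKM, the log2 fold was 8.77 and 5.00 for g1861, 3.07 and 2.04 for g6744, -9.83 and -6.80 for g6354, and -8.96 and -6.07 for g7305. All 4 genes also passed in the paired fit, with adjusted p between 0.00306 and 0.0104. Without library 2 of pH 5.7, g6744 and g6354 missed the threshold (limma adjusted p = 0.0567 and 0.0539), and so did g6354 without library 3 of pH 7.6 (0.0545). With the numbered libraries alone, g1861, g6744 and g6354 missed it (0.0804, 0.0585 and 0.0742), while every fold kept its direction.

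With libraries compared within pairs, 883 M. conductrix genes, or 10.4% of those tested, changed with pH, 411 higher and 472 lower at pH 5.7. All 95 genes of the unpaired fit were among them. The added genes changed less: the median log2 fold of the paired calls was 0.61 for the higher and -0.79 for the lower genes, and 67 and 179 of them at least doubled or halved. By expression level, 98 of the 1297 genes at 100 FPKM or more were higher and 93 lower. Among the 6018 genes at 10 to 100 FPKM, 294 were higher and 316 lower, and among the 1185 genes below 10 FPKM, 19 were higher and 63 lower. In 20% of genes the values of both pH groups did not overlap, where chance gives 10% for exchangeable libraries. Values simulated with the pairs and no pH effect gave 2.35%, which may be too low. In all 3 pairs, 56% of genes moved in the same direction, where chance gives 25%. Genes of the same libraries vary together, so these shares were not tested against chance. Scaling to equal totals, which moved the median log2 fold of all genes to 0.06, gave 623 higher and 467 lower genes with this shift not subtracted. Without a mean-variance trend the paired fit called 145 higher and 248 lower genes, without a filter on low values 150 and 233, and with sample quality weights 1128 and 1114.

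The unpaired count varied with the libraries that entered it. It was 2 higher and 12 lower genes without library 2, 4 and 15 without library 4, and 4 and 15 without library 3. Without library 57 it was 14 and 64, without library 1 it was 14 and 55, and without library 76 it was 19 and 62. In the numbered libraries alone it was 9 and 40, while libraries 57 and 76 alone, 1 per pH, allowed no test. The paired count was 192 and 386 without libraries 1 and 2, 54 and 94 without libraries 3 and 4, and 219 and 389 without libraries 57 and 76. Of the 883 genes called with all pairs, 388, 146 and 441 were still called in these 3 fits.

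In C. sorokiniana no gene passed the threshold without pairing (limma, 9011 genes). At an unadjusted p under 0.05 there were 675 genes, or 7.49%, and the smallest adjusted p was 0.0663. Without library 57 the unpaired fit called 4 higher genes and 1 lower gene, and without library 76 it called 0 and 2. Scaling to equal totals, which moved the median log2 fold of all genes to 0.49, gave 40 higher and 2 lower genes with this shift not subtracted. Sample quality weights gave 133 and 131. With libraries compared within pairs, 94 genes changed, 81 higher and 13 lower at pH 5.7. All 94 at least doubled or halved, with a median log2 fold of 3.17 for the higher and -3.63 for the lower genes, and 11 rose and 4 fell at least 16-fold. The paired count was 33 and 8 with a pseudocount of 0.1 FPKM or with quantile normalization, 34 and 3 with a pseudocount of 5 FPKM, and 42 and 7 among genes with a mean of at least 5 FPKM. With sample quality weights it was 892 and 660. Of the 81 higher genes, 25 averaged below 10 FPKM, 51 lay at 10 to 100 FPKM and 5 at 100 FPKM or more, and the 13 lower genes numbered 1, 6 and 6 in these ranges. The values of both pH groups did not overlap in 11.8% of genes, where chance gives 10% for exchangeable libraries. Values simulated with the pairs and no pH effect gave 3.16%, which may be too low. In all 3 pairs, 35.3% of genes moved in the same direction, where chance gives 25%. As in M. conductrix, these shares were not tested against chance.

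The 4 C. sorokiniana genes named here were chosen after the values were seen, and none passed without pairing (adjusted p between 0.0663 and 0.138). Gene g5259 was at 1910 ± 1890 FPKM (SD, n = 3) at pH 5.7 and at 33.4 ± 28.6 FPKM at pH 7.6, a log2 fold of 6.13 (SE 0.63 within pairs; limma adjusted p = 0.0269). It rose in 3 of 3 pairs, by 4.53 to 7.75. Gene g432 stood at 70.2, 629 and 205 FPKM in libraries 2, 4 and 57, against a listed 0 and 2.86 and 8.12 FPKM in libraries 1, 3 and 76 (log2 fold 6.00, SE 0.55; limma adjusted p = 0.0265). Gene g223 fell from 804 ± 648 FPKM at pH 7.6 to 7.11 ± 9.81 FPKM at pH 5.7 (log2 fold -6.63, SE 0.77; limma adjusted p = 0.0391). Gene g6470 fell from 458 ± 206 to 6.28 ± 4.63 FPKM (log2 fold -6.08, SE 0.45; limma adjusted p = 0.0229). These 4 genes missed the threshold in paired fits without libraries 1 and 2 (adjusted p between 0.106 and 0.108) and without libraries 3 and 4 (0.201 to 0.223), and no gene passed in either. With a pseudocount of 0.1 and of 5 FPKM, the log2 fold was 6.30 and 5.68 for g5259, 7.28 and 4.75 for g432, -7.08 and -5.63 for g223, and -6.35 and -5.33 for g6470. In addition g432 missed it with a pseudocount of 0.1 FPKM (0.0537), and g223 with a pseudocount of 0.1 or 5 FPKM, with no filter and with quantile normalization (0.0515 to 0.0573).

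**Figure D2:**
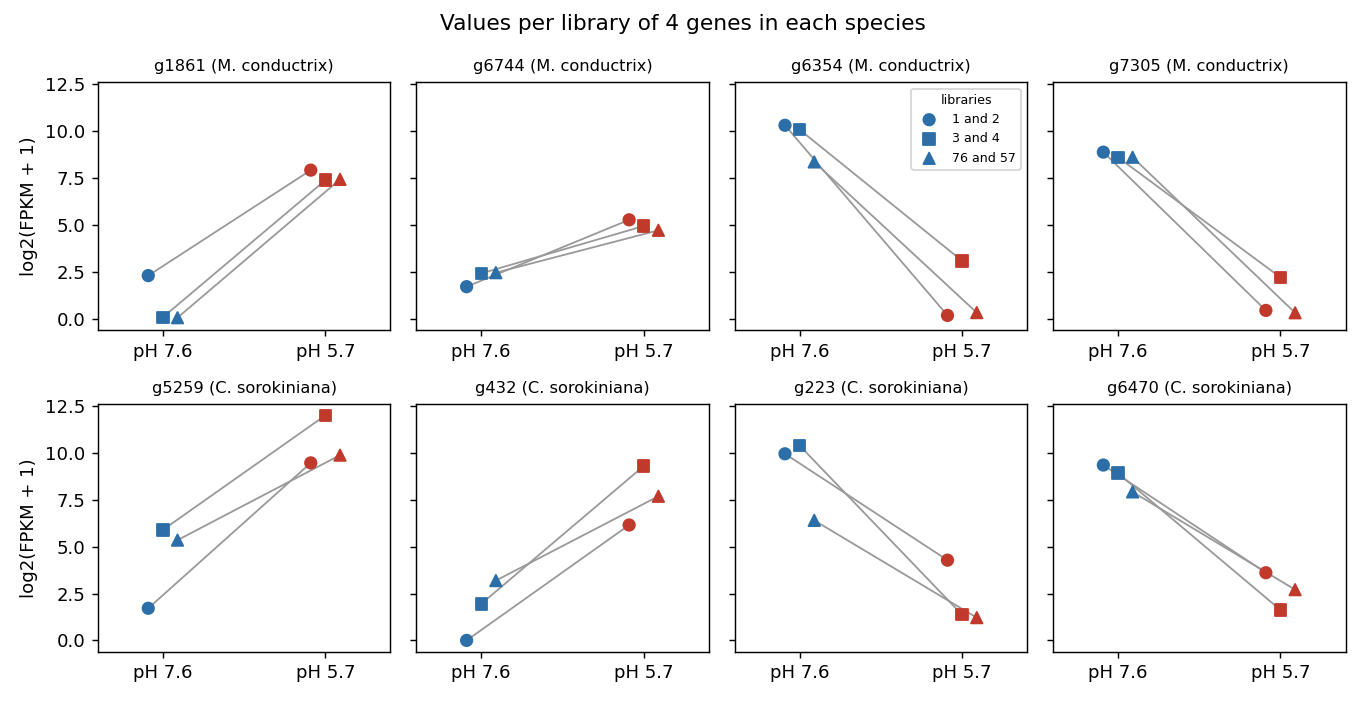
Each panel shows log2(FPKM + 1) of a named gene at pH 7.6 and pH 5.7, with M. conductrix above and C. sorokiniana below; symbols mark the pair of libraries and lines join its members. In all 8 genes the 3 lines slope the same way, as for g7305, which fell from 416 to 1.4 FPKM.

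Libraries 57 and 76 of C. sorokiniana stood apart from the rest and changed the number of genes called. In library 76, grown at pH 7.6, the 50 most abundant genes held 67.4% of all FPKM, and in library 57, grown at pH 5.7, they held 47.2%, against 28.4% to 33.2% in the numbered libraries. The FPKM of library 76 summed to 1664102, against 766511 to 1074955 in the other 5. Without this pair, the paired fit called 548 genes higher and 539 lower at pH 5.7, a total of 1087 that included all 94. That fit had 2 libraries per pH. In a simulation of it 58 of 203 calls were false, but the simulated spread came from all pairs, libraries 57 and 76 included. That share therefore need not hold for the 1087 genes. With the pH of libraries 3 and 4 exchanged, the same fit called 0 genes, but this is a single other split. Scaling each library to equal totals moved the median log2 fold of all genes to 0.49, and the paired fit, with this shift not subtracted, then called 200 higher and 15 lower genes.

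**Figure D3:**
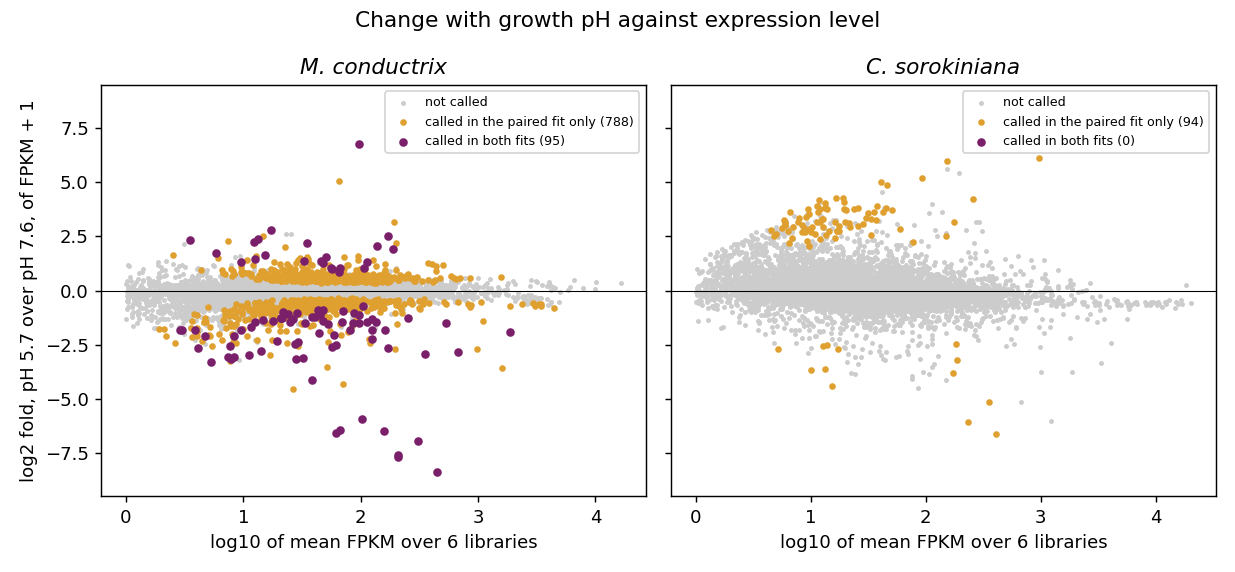
Each point is a gene, with its mean FPKM over 6 libraries on a log10 axis and its log2 fold at pH 5.7 over pH 7.6, of FPKM + 1; purple points passed in both fits and orange points in the paired fit only. M. conductrix has 95 purple points, which reach -8.39, and C. sorokiniana has none and 94 orange points, 81 of them above 0.

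Side by side, 10.4% of M. conductrix genes and 1.04% of C. sorokiniana genes changed with pH in the paired fits. The median absolute log2 fold was 0.21 in the first and 0.32 in the second. The shares were 6.8% and 0% without libraries 1 and 2, and 1.74% and 0% without libraries 3 and 4. Without libraries 57 and 76 the order was the opposite, at 7.17% and 12.1%, in fits of 2 libraries per pH. Simulations of these fits gave 8 false calls of 202 in M. conductrix and 58 of 203 in C. sorokiniana. Their spread came from all pairs, libraries 57 and 76 included, so these shares need not hold for the real fits. The median SD within pairs was 0.13 on the log2 scale in M. conductrix and 0.36 in C. sorokiniana. A simulated log2 change of 1 was recovered by the paired fit, under its own assumptions, in 90% and in 8% of changed genes. Whether the pH response differed between the species was not tested, because genes were not matched between the tables. Each species was also a single strain, and the labels word the growth media differently, so species cannot be told apart from strain or medium.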

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

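The alternatives run with the replicate block, the pairs left out and the numbered libraries alone were added after the data were seen. Without pairing, the 23 higher and 72 lower M. conductrix genes stayed within 1.5 times under a pseudocount of 0.1 or 5 FPKM, both filters, 3 scalings, no trend and a required doubling or halving. They became 81 and 225 with sample quality weights, 76 and 150 with the naming style as a covariate, 411 and 472 with the replicate block, and 9 and 40 in the numbered libraries alone. Leaving out 1 library gave 2 to 19 higher and 12 to 64 lower genes. The absence of calls in C. sorokiniana became 1 higher and 2 lower genes with upper-quartile scaling and with quantile normalization, 40 and 2 with equal totals, 133 and 131 with sample quality weights, 81 and 13 with the replicate block, and 4 and 1 in the numbered libraries alone. Leaving out 1 library gave 0 to 4 higher and 0 to 2 lower genes. Scaling to equal totals moved the median log2 fold of all C. sorokiniana genes to 0.49, and this shift was not subtracted.

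With the replicate block, the 411 and 472 M. conductrix genes became 150 and 233 with no filter, 145 and 248 with no trend, 623 higher with equal totals, 1128 and 1114 with sample quality weights, and 67 and 179 with a required doubling or halving. They became 192 higher without libraries 1 and 2, 54 and 94 without 3 and 4, and 219 higher without 57 and 76. The 81 and 13 C. sorokiniana genes became 33 and 8 with a pseudocount of 0.1 FPKM and with quantile normalization, 34 and 3 with a pseudocount of 5 FPKM, 8 lower with no filter, 42 and 7 with a mean of at least 5 FPKM, 200 higher with equal totals, and 892 and 660 with sample quality weights. They became 0 and 0 without libraries 1 and 2 and without libraries 3 and 4, and 548 and 539 without 57 and 76. The cause of these shifts was not tested. No named gene changed direction under any alternative run. Fits that left out a library or pair rest on fewer samples, and a paired fit on 4 libraries leaves 1 residual degree of freedom, so it leans on the spread shared across genes. The replicate block changed no call of the 4 named M. conductrix genes. Tests of gene lists and orthologs, and their alternatives, were not run, because the files pair identifiers with no names or sequences. With depth unknown, changes of genes near 1 FPKM cannot be set against counting error.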

Other observations

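All tests in this part were chosen after the results they bear on were seen. The 50 most abundant genes of library 76 of C. sorokiniana, grown at pH 7.6, took 67.4% of FPKM there and 46.7% in library 57, against 19.8%, 23.5%, 28.3% and 29.9% in libraries 1, 2, 3 and 4. Growth pH alone cannot give an excess of library 76 over libraries 1 and 3, whichever genes are chosen, because these libraries shared pH 7.6. The 50 most abundant genes of library 57 were chosen without library 76 but share 48 with its list. In them, libraries 1 and 3 exceeded libraries 2 and 4 by a median log2 fold of 0.19 (quartiles 0.12 and 0.29). Library 76 exceeded libraries 1 and 3 by 2.00 (quartiles 1.74 and 2.33). In the list of library 76, library 57 exceeded libraries 2 and 4, all at pH 5.7, by a median of 0.95, in 50 of 50 genes, so a difference shared by libraries 57 and 76 may be part of the pattern. Low depth would scatter values up and down rather than raise abundant genes together. In the list of library 57, library 76 exceeded libraries 1 and 3 in 48 of 50 genes, which argues against a shallow library as the source. The depth itself is uncertain. That of library 76 was estimated at 1.49 times that of library 1, with no known spread, and another estimate in this species was uncertain by a factor of 2. Whether the shared difference is a sequencing run, a growth stage or another culture is open, because the labels give no batch and say only that harvest times were similar.

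The 10 M. conductrix genes that differed at least 16-fold between the pH groups and were called without pairing had log2 folds of 4.12 or more. A difference in depth or scaling between libraries would move genes of like level alike. Other genes within 2-fold of each one's level (149 to 2963 genes) moved in its direction by a median log2 fold of at most 0.07. Library medians were alike as deposited, so a small median was largely given in advance. It leaves no shift common to genes of like level that could give these folds. The 99th percentile of the other genes was at most 2.78, but for 1 of the 10 genes a gene of like level moved as far. If reads of another organism of constant make-up in the pH 7.6 cultures were the source, the falling genes would share 1 ratio between libraries 76 and 1. The ratios of the 9 falling genes spanned 2.86 on the log2 scale. A response to growth pH remains a hypothesis, and a contaminant whose own genes vary between cultures was not excluded.

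Genes with consecutive numbers tended to change together, which is of interest because running numbers may follow the order of genes along a genome. Among contrasts of the libraries, only that of pH was examined, so this tendency is not shown to be particular to growth pH. Spearman's rho of the fold change across consecutive genes, which are not independent replicates, was 0.072 in M. conductrix and 0.102 in C. sorokiniana, each with a permutation p of 0.001, the smallest that 1000 shuffles can give, and an adjusted p of 0.005 over 20 correlations. In the paired fit of M. conductrix, 76 neighbouring couples were called in the same direction, against a mean of 43 and a maximum of 66 in shuffled orders, while the unpaired calls of M. conductrix and the paired calls of C. sorokiniana held 2 such couples each, within the shuffled range (permutation p = 0.129 and 0.152). Mean levels of consecutive genes correlated too (rho 0.086 and 0.065, both above shuffled orders), and at a distance of 2 numbers as well (0.035 and 0.030, adjusted p = 0.00857 for both), so 1 transcript split over 2 gene models, or shared reads, cannot be told apart from co-regulated neighbours without gene positions. At a distance of 2 numbers rho of the fold change was 0.009 in M. conductrix, within the shuffled range, and 0.027 in C. sorokiniana, above it (permutation p = 0.012, adjusted p = 0.024), as it was there at distances of 3 and 4 (0.026 and 0.031, adjusted p = 0.024 and 0.00857), where 1 transcript split over 2 consecutive models would give none; the difference between the species was not tested.

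Other groupings of the libraries were also compared. Among the 10 splits of the 6 M. conductrix libraries, 3 against 3, the real one called 95 genes and the highest other called 0, so 1 split had as many. With pairing, the real split called 883 genes and the highest of the other splits that part all pairs called 0, again 1 split, of 4. In C. sorokiniana the real split called 0 genes without pairing, so all 10 splits had as many, and the highest other, libraries 2, 57 and 76 against 1, 3 and 4, called 2. With pairing it called 94 against 0, 1 split of 4. These splits are too few for a share under 0.05.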
